A study of Mus musculus with 16 samples.

How the data were processed

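H3K4me3 was measured by chromatin immunoprecipitation and single-end sequencing in 12 hippocampal libraries from adult male mice, and H3K4me1 and Kdm5C were measured in 2 libraries each. The libraries of a group are separate pools, and each pool held 2 mice per the series design. The H3K4me3 groups, with 2 libraries each, were WT and Kdm5c KO under standard conditions, WT and Kdm5c KO after exposure to novelty, the line the labels call ifKO, and its controls, written ifWT here. The KO cohort had a mixed C57 and 129 background per the labels, whereas the ifKO cohort and the H3K4me1 and Kdm5C libraries were C57BL/6J. How the ifKO line was made is not given in the sources used here. The title of 1 ifWT library reads H3K3me3, but its antibody label reads H3K4me3 and it was used as such.

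The deposited H3K4me3 files hold 1 read count per region and library, without normalization, for one shared set of regions per the file headers. The deposited H3K4me1 and Kdm5C files hold a signal per region that the file headers call raw counts, but the values behave as summed base coverage over 2321 regions shared by both marks. Those values were therefore read as covered bases, and 50 covered bases were taken as 1 read equivalent. Per the submitters' processing notes, Bowtie2 2.2.9, SAMtools 1.3.1, MACS2 2.1.0, DESeq2 1.10.0 and R 3.3 were used upstream, with featureCounts for the H3K4me1 and Kdm5C libraries, and the genome build was mm10. How the regions were defined is not given in the sources used here. No input libraries were used here.

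Each H3K4me3 file lists 36005 regions, of which 9 repeat another one with identical counts in all 12 libraries. These repeats were removed, which left 35996 regions with a median width of 1019 bp (218 to 5340 bp). A gene table of the GRCm38 build with 49943 genes and no strand column was used for annotation. A region was therefore assigned to a gene end when it lay within 2 kb of either end of a gene, otherwise to the gene that contained it, otherwise to the nearest gene within 50 kb. The plan fixed before the data were examined spoke of transcription start sites, and gene ends replaced them because the table gives no strand. Gene ends held 19846 regions (55.1%), the inside of genes 10362 (28.8%), and 5788 (16.1%) lay between genes.

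Total counts over the regions ranged from 18181192 to 30435735 per H3K4me3 library, and a floor of 3 counts corresponded to 0.0986 to 0.165 CPM, the count scaled to a common library size. Exact Poisson intervals at 95% were computed for low counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The library totals behind the H3K4me1 and Kdm5C values are unknown, because these files cover only part of each library.

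All 12 H3K4me3 libraries were fitted together in edgeR 4.0.16 under R 4.3.3, with 1 mean per group, TMM scaling factors, filterByExpr, quasi-likelihood F tests and a Benjamini-Hochberg threshold of 0.05. The filter removed 41 regions and left 35955. A region is said to have risen or fallen, or to be called, when its adjusted p was under that threshold. Standard errors of log2 changes were derived from the F statistic. CPM values use the TMM-scaled library sizes and are given with the SD of the 2 libraries. The tested comparisons were KO against WT under standard conditions, after novelty and averaged over both, novelty against standard conditions in WT, in KO and averaged over both, the interaction of genotype and novelty, ifKO against ifWT, and the KO effect under standard conditions minus the ifKO effect. With 2 libraries against 2, no permutation of a single region could reach the threshold, and the tests rest on a spread estimated across all groups and regions.

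There were 17 gene lists, covering germline and meiosis genes, activity-induced genes, pyramidal and granule neuron genes, markers of interneurons, astrocytes, the oligodendrocyte lineage, microglia, vascular cells and pericytes, choroid plexus and ependyma, and striatum, thalamus and hindbrain, H3K4 methylation enzymes, clustered protocadherins, developmental transcription factors, synaptic transmission genes, ribosomal protein genes, neuronal intellectual disability genes, and interferon and innate immune genes. Each gene was represented by the gene-end region with the most counts, and genes without a gene-end region were not tested. Lists were tested against the regions that represented all other genes in this way, and position classes against all other regions. Both used camera in limma 3.58.1 with a preset correlation of 0.01, and again an estimated correlation and fry. Members were also counted with p values adjusted over the list alone. Concordance was computed across regions between comparisons that share no library.

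Genes were named by a rule. In each tested comparison it took regions past the threshold with a mean log2 CPM of at least 1, a gene, and no overlap between the libraries of both groups, and from these the 10 largest positive and the 10 largest negative log2 changes with 1 region per gene. For the interaction and the difference of the lines, overlap between libraries was not considered. Where fewer than 3 regions passed, the 5 smallest p values were taken instead. Up to 4 called members per list were added, and Kdm5c, Fos, Arc, Npas4, Egr1, Bdnf, D1Pas1, Cyct, Dazl and Ddx4 were always followed. The grouping, tests, lists, naming rule and most alternatives were fixed before the data were examined.

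Single H3K4me1 and Kdm5C libraries were compared without a test, as log2 ratios of KO to WT after scaling to the file total, with a prior of 1 read equivalent, for regions with at least 50 summed read equivalents, and with exact binomial intervals at 95% for single regions. The prior was added before scaling. Intervals at 95% of a median were taken from the ranks of the regions. They treat regions as independent and leave out variation between libraries. H3K4me3 regions overlapping Kdm5C regions with a WT to KO ratio of at least 2 formed a set for camera, with an overlap of at least 1 bp.

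Alternatives were RLE factors, unscaled library totals, loess offsets that depend on region strength, no filter, a mean log2 CPM of at least 2, DESeq2 1.42.0, limma-voom, fits to the compared groups or to the same cohort, a replicate block, each library left out in turn, a threshold of 0.1, an added minimum log2 change of 0.5, gene-end windows of 1 and 5 kb, other Kdm5C ratios, and other scalings and minimums for the single libraries. With 1 library left out, the remaining library of its group was assumed to vary like the other groups. Chosen after seeing the data were the Kdm5C set without a ratio, the set from unscaled ratios, and the fit without the Camk2a neighbourhood and the 20 largest regions. Correction for GC content was planned but not run, because no genome sequence was used here. The edgeR procedure was tested on simulated data, in which regions changed by 2-fold were called in 58% of cases in the design of KO against WT under standard conditions and in 70% in that of ifKO against ifWT. False calls made up 10.5% and 12.8% of the simulated calls in these designs, 9.40% in that of novelty in WT and 8.84% in that of the averaged genotype. In each simulated design 50 regions each were changed by 1.25-, 1.5-, 2- and 4-fold and the regions of 1 list by less. Most of the 35955 regions were left unchanged, so these shares need not hold for the real calls. Tables and plots used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.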

Results

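H3K4me3, a histone mark found at active promoters, was profiled by ChIP-seq in the hippocampus of adult male mice. WT mice and mice lacking Kdm5c, an X-linked gene for an enzyme that removes methyl groups from H3K4, were sampled under standard conditions and after 1 h in a box with unfamiliar objects, called novelty here. The line the labels call ifKO and its controls (ifWT) were sampled under standard conditions. Each of these 6 groups had 2 libraries. H3K4me1, a mark common at enhancers, and Kdm5C itself were profiled in 1 WT and 1 KO library each. Counts over the H3K4me3 regions totalled 22055154 and 22566171 in WT under standard conditions, 23680512 and 26433417 in KO under standard conditions, 23265704 and 29105241 in WT after novelty, and 30435735 and 23914024 in KO after novelty. They totalled 21303898 and 22996995 in ifWT and 20154739 and 18181192 in ifKO. Libraries of a group correlated with r from 0.987 to 0.992 across regions, which are not independent replicates. The variance between the libraries of a group, relative to that from counting error (chi-square per degree of freedom), was largest in ifKO, at 7.33 times. It was 4.32 times in ifWT and 2.2 to 2.76 times in the KO cohort.

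H3K4me3 at the end of Kdm5c itself (chromosome X, 152232907 to 152234889 of mm10) was 60.5 ± 0.396 CPM in KO and 69.4 ± 3.96 CPM in WT under standard conditions (SD, n = 2 each). The log2 change was -0.20 ± 0.07 (SE) with an edgeR adjusted p of 0.047. That call was lost without WT standard replicate 1 (0.061) or 2 (0.397) and without KO standard replicate 1 (0.142) or 2 (0.152), with DESeq2 (0.062), with limma-voom (0.057), with scaling by library totals and with offsets fitted to region strength. After novelty the change was -0.15 ± 0.07 (adjusted p 0.12), and in ifKO -0.08 ± 0.07 (adjusted p 0.58). A mark at the end of the gene does not report on a deletion inside it.

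The first comparison asked where H3K4me3 differed in Kdm5c KO mice under standard conditions. The largest rise among the named genes was at a region nearly silent in WT. A region inside Ssh1, which encodes a phosphatase acting on the actin regulator cofilin (chromosome 5, 113942805 to 113943958), had 7.23 ± 1.45 CPM in KO and 0.179 ± 0.064 CPM in WT (SD, n = 2 each), a log2 change of 5.29 ± 0.37 (SE, adjusted p 1.8e-12). H3K4me3 at the end of Zfp532, a zinc finger gene (chromosome 18, 65578583 to 65579249), rose from 1.52 ± 0.121 to 20.4 ± 3.29 CPM, a log2 change of 3.74 ± 0.19. The region at the shared end of Cacng6, a calcium channel subunit gene, and 3300002P13Rik (chromosome 7, 3423573 to 3425168) rose from 3.45 ± 0.14 to 32.5 ± 2.28 CPM, a log2 change of 3.23 ± 0.15. Glp2r, the receptor gene for a gut peptide hormone, rose by 3.43 ± 0.25 on the log2 scale and the shared end of Gins2 and Gse1 by 3.81 ± 0.28. Among the falls, the end of Ogn, which encodes an extracellular matrix proteoglycan (chromosome 13, 49608272 to 49610082), went from 6.47 ± 0.958 to 1.62 ± 0.0902 CPM, a log2 change of -1.99 ± 0.29 (adjusted p 6.6e-06).

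In all, 4821 of 35955 regions were called by edgeR, 3501 higher and 1320 lower in KO, and 10054 had an unadjusted p under 0.05. A change of at least 2-fold was reached by 1421 of the higher and 30 of the lower regions. The share of called regions that were higher was 72.6%, against 89.8% when libraries were scaled by their totals. Called counts were 3657 with DESeq2 and 4723 with limma-voom. The lower regions were the less stable part, with 2131 higher and 401 lower without WT standard replicate 1 (2532 in all), 1851 and 133 without WT standard replicate 2 (1984), 2181 and 364 without KO standard replicate 1 (2545), and 2830 and 685 without KO standard replicate 2. In simulated data of this design, 10.5% of calls were false.

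**Figure D1:**
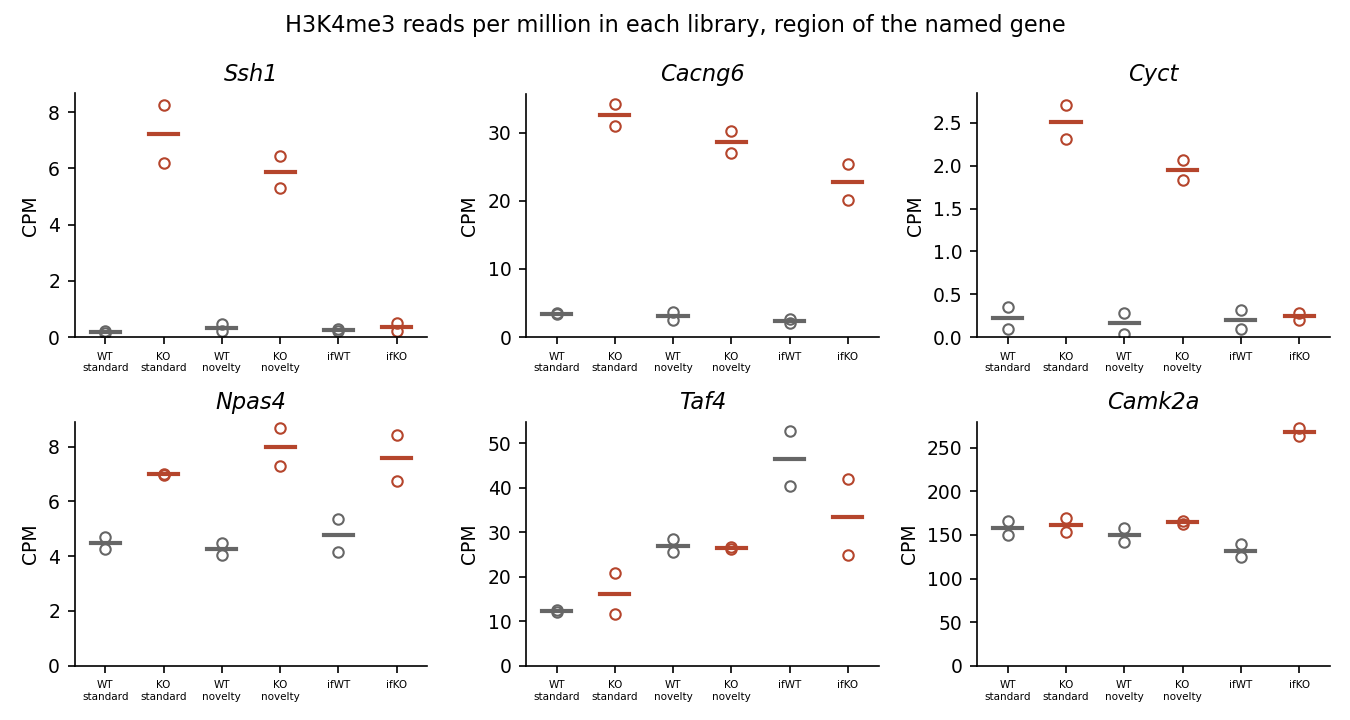
H3K4me3 (CPM) of each library, by group, at the regions of Ssh1, Cacng6, Cyct, Npas4, Taf4 and Camk2a, where circles are libraries and lines are group means of 2 libraries. Camk2a averaged 268 CPM in ifKO and 132 CPM in ifWT.

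The changes varied with the position and strength of regions, but the calls by position were lost with offsets fitted to strength. Of 19837 gene-end regions 1683 rose and 1187 fell. Of 10344 regions inside genes 1195 rose and 96 fell, and of 5774 regions between genes 623 rose and 37 fell. The medians were -0.05, 0.14 and 0.16 log2, and camera placed gene ends lower (adjusted p 4.5e-05) and regions inside genes (0.0019) and between genes (0.0050) higher than the rest. With an estimated correlation these became p = 0.0583, p = 0.116 and p = 0.193, and with offsets fitted to region strength the adjusted p were 0.25, 0.25 and 0.53. The 960 X-linked regions had a median of -0.02 and 61 rose and 27 fell (camera adjusted p 0.186). The 10587 weakest regions, below a mean log2 CPM of 1, had a median change of 0.19 with 719 higher and 27 lower, whereas the 6111 strongest, above 6, had a median of -0.09 with 124 higher and 774 lower.

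**Figure D2:**
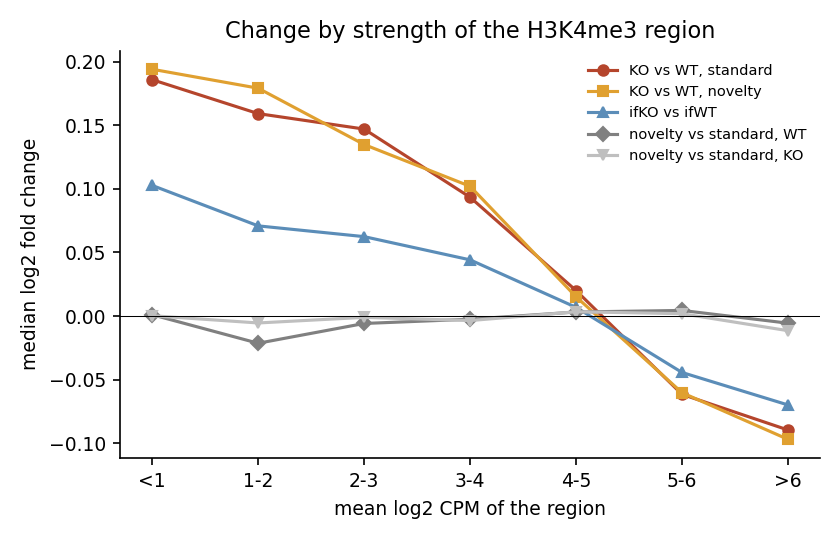
Median log2 change of H3K4me3 (vertical axis) of regions grouped by mean log2 CPM (horizontal axis), with 1 line per comparison. Under standard conditions the KO line falls from 0.19 in the weakest to -0.09 in the strongest regions, and the novelty lines stay near 0.

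Among the lists, germline and meiosis genes, which are normally silent in brain, rose in KO. Of 21 measured members 9 were higher and 0 lower by edgeR (10 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.45. The camera adjusted p was 1.2e-08, and the call held with an estimated correlation (adjusted p 0.0087). The list held 44 genes, and those without a gene-end region were not tested, so these values describe the measured members only. How regions were defined is not given, so whether members entered through signal in KO alone cannot be told. D1Pas1, a testis RNA helicase gene (chromosome 1, 186967324 to 186968158), had 3 and 1 counts in WT, a pooled 0.0896 CPM (95% interval 0.0244 to 0.229), and 64 and 78 counts in KO, a pooled 2.75 CPM (2.32 to 3.24), with a fitted log2 change of 4.86 ± 0.52. Cyct, the testis cytochrome c gene (chromosome 2, 76359863 to 76360580), had 2 and 8 counts in WT, a pooled 0.224 CPM (0.107 to 0.412), and 66 and 63 in KO, a pooled 2.50 CPM (2.09 to 2.97). Ddx4, a germ cell helicase gene, rose by 2.24 ± 0.40 on the log2 scale, and Sycp3, which encodes a protein of the meiotic chromosome axis, by 1.61 ± 0.25. The shared end of Tex14 and Rad51c rose from a higher level, 31.1 to 47.3 CPM. Dazl, a germ cell RNA-binding protein gene, had a log2 change of 0.24 ± 0.09 (adjusted p 0.070).

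**Figure D3:**
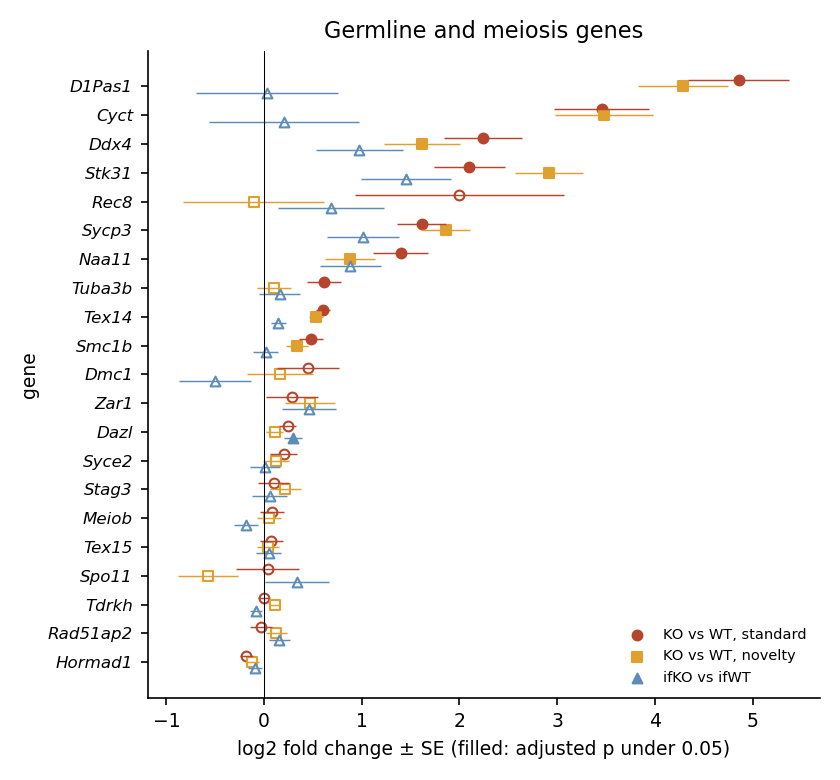
Log2 change of H3K4me3 (horizontal axis) of the 21 germline and meiosis genes with a gene-end region (vertical axis) in KO under standard conditions, KO after novelty and ifKO, with bars of 1 SE and filled symbols for adjusted p under 0.05. D1Pas1 lies at 4.86 and 4.29 in the KO comparisons and at 0.03 in ifKO.

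Ribosomal protein genes were lower on balance, with 0 of 43 higher and 10 lower (0 and 13 adjusted over the list alone; median -0.10, camera adjusted p 0.0039). That list call was lost with an estimated correlation (p = 0.238) and with offsets fitted to region strength (adjusted p 0.28). Among H3K4 methylation enzymes, the shared end of Setd1b, a methyltransferase gene, and Rhof (chromosome 5, 123138457 to 123140577) rose from 102 ± 1.26 to 149 ± 3.63 CPM, a log2 change of 0.55 ± 0.05 (adjusted p 1.9e-09), while 5 of the 18 members fell (median -0.10, camera adjusted p 0.21; 1 higher and 7 lower adjusted over the list alone).

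Lists of brain cell types had few called members and no list call. Pyramidal and granule neuron genes had 1 of 26 higher and 1 lower (the same adjusted over the list alone, median -0.07) and interneuron markers 1 of 16 higher and 1 lower (the same adjusted over the list alone, median -0.02, although camera placed the list slightly up with an adjusted p of 0.89). Astrocyte markers had 2 of 13 higher (2 higher and 1 lower adjusted over the list alone, median 0.10), with the shared end of Ntsr2 and Lpin1 higher by 0.46 ± 0.08. Oligodendrocyte lineage markers had 1 of 15 higher (1 adjusted over the list alone, median -0.12), which was Gpr17, a receptor gene of immature oligodendrocytes, from 8.83 to 14.7 CPM. Microglia markers had 2 of 18 higher (2 adjusted over the list alone, median 0.03). Vascular and pericyte markers had 1 of 18 higher and 3 lower (1 and 7 adjusted over the list alone, median -0.23), with Sox18, an endothelial transcription factor gene, at 0.51 ± 0.07 and Tbx18, a mural cell transcription factor gene, at -0.79 ± 0.14. Choroid plexus and ependymal markers had 2 of 7 higher (3 adjusted over the list alone, median 0.22), among them the shared end of Ccdc153 and Pdzd3 at 1.11 ± 0.22. Striatal, thalamic and hindbrain markers had 1 of 14 higher (1 adjusted over the list alone, median 0.11). The camera adjusted p of these lists lay between 0.074 and 0.89.

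The other lists were not called either. Activity-induced genes had 2 of 39 higher (2 adjusted over the list alone, median 0.01), Dusp5, a phosphatase gene, at 0.35 ± 0.06 and Npas4, a transcription factor gene induced by neuronal activity, at 0.64 ± 0.18 (adjusted p 0.013). The Npas4 call was lost without WT standard replicate 1 (0.117) or 2 (0.0651) and without KO standard replicate 1 (0.0568) or 2 (0.0528). Fos, Arc, Egr1 and Bdnf, which respond to neuronal activity, had changes of 0.10 (adjusted p 0.36), 0.07 (0.43), -0.04 (0.76) and -0.27 (0.17). Clustered protocadherins had 2 of 45 regions higher (2 adjusted over the list alone, median 0.01, camera adjusted p 0.33) and developmental transcription factors 0 of 21 in either direction (0 adjusted over the list alone, median 0.03, camera adjusted p 0.63). Synaptic transmission genes had 1 of 34 lower (0 adjusted over the list alone, median -0.04, camera adjusted p 0.82), neuronal intellectual disability genes 2 of 23 lower (1 adjusted over the list alone, median -0.10, camera adjusted p 0.074), and interferon and innate immune genes 2 of 23 lower (2 adjusted over the list alone, median -0.11, camera adjusted p 0.39).

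The same question was asked after novelty, in separate libraries. H3K4me3 inside Ssh1 was 5.87 ± 0.821 CPM in KO and 0.337 ± 0.181 CPM in WT (SD, n = 2 each), a log2 change of 4.16 ± 0.32 (SE, adjusted p 2.2e-11), and Zfp532 rose by 3.57 ± 0.19 and Glp2r by 3.22 ± 0.24. Npas4 rose from 4.27 ± 0.308 to 7.99 ± 0.961 CPM, a log2 change of 0.89 ± 0.17 (adjusted p 0.00028), while Fos (0.09), Egr1 (-0.13) and Bdnf (-0.22) were not called. Neurod6, a transcription factor gene of pyramidal neurons, rose by 0.38 ± 0.08 and Setd1b by 0.69 ± 0.05. Among germline and meiosis genes 8 of 21 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.16, camera adjusted p 7.5e-07, and 0.0164 with an estimated correlation), with D1Pas1 at 4.29 ± 0.46, Stk31, a testis kinase gene, at 2.92 ± 0.35 and Sycp3 at 1.86 ± 0.25. Restricted to regions with a mean log2 CPM of at least 2, the germline list had an adjusted p of 0.13.

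After novelty 6118 regions were called by edgeR, 3981 higher and 2137 lower in KO, with 4930 by DESeq2 and 6939 by limma-voom. The share of called regions that were higher was 65.1%, against 82.1% with scaling by library totals, and the count was 2239 without WT novelty replicate 2, 2933 without KO novelty replicate 1 and 3321 without KO novelty replicate 2, of which 275, 492 and 642 were lower. Across regions the KO changes under both conditions correlated with r 0.713 and rho 0.609. Both comparisons called 2615 regions higher (388 expected from independent calls) and 549 lower (78.5 expected), and 0 were called in opposite directions. The expected counts leave out that weak and strong regions were called at unlike rates. Averaged over both conditions, 11528 regions differed, 6519 higher and 5009 lower, and the higher share of 56.5% became 74.0% with scaling by library totals and 49.9% with RLE factors. The majority turned with RLE factors, at 6196 higher and 6223 lower, and with DESeq2, at 4812 higher and 5024 lower. The lower count was 3173 without WT standard replicate 2 and 2904 without WT novelty replicate 2. In that average Ssh1 rose by 4.72 ± 0.25, Cacng6 by 3.20 ± 0.11 and Npas4 by 0.77 ± 0.12 on the log2 scale.

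The novelty comparison asked whether 1 h in an unfamiliar setting shifted H3K4me3. In WT, edgeR called 2 regions, both higher after novelty. That count depended on the libraries in the fit, with 106 regions (78 higher and 28 lower) in a fit to the compared groups alone and 47 (40 higher and 7 lower) in a fit to the KO cohort, and it was 6 with offsets fitted to region strength. The spread shared with the more variable libraries of ifKO and ifWT could lower the count in the main fit. The end of Taf4, a gene for a general transcription factor (chromosome 2, 179975979 to 179976693), rose from 12.3 ± 0.303 to 27.0 ± 2.17 CPM (SD, n = 2 each), a log2 change of 1.13 ± 0.18 (SE, adjusted p 0.011), and Pde10a, a phosphodiesterase gene (chromosome 17, 8524069 to 8527904), from 74.0 ± 3.40 to 95.9 ± 1.05 CPM, a change of 0.37 ± 0.06 (adjusted p 0.011). Fos had 54.7 ± 2.2 CPM after novelty and 47.5 ± 2.77 CPM under standard conditions (0.20 ± 0.07, adjusted p 0.70), and Arc (-0.02), Npas4 (-0.07), Egr1 (0.04) and Bdnf (-0.10) lay closer to 0. Taf4 was lost without WT standard replicate 1 (0.831) or 2 (0.258), without WT novelty replicate 1 (0.117) or 2 (0.573), with DESeq2 (1) and with limma-voom (0.19), and Pde10a without WT standard replicate 1 (1) and WT novelty replicate 1 (0.159) or 2 (0.442). The count in WT was 0 without WT standard replicate 1 and without WT novelty replicate 1 or 2, and DESeq2 and limma-voom called 1 region each, while 1679 regions had an unadjusted p under 0.05. In KO, edgeR called 0 regions (1416 at an unadjusted p under 0.05, 1 each by DESeq2 and limma-voom, 5 in a fit to the KO cohort, 4 without KO standard replicate 1 and 2 without KO standard replicate 2). The smallest p in KO belonged to Pde10a (0.33 ± 0.06, adjusted p 0.079), followed by Phactr3, Hsph1 and Nr4a1, each with an adjusted p of 0.22. For the interaction of genotype and novelty edgeR called 0 regions, as did DESeq2 and limma-voom, 1055 had an unadjusted p under 0.05, and 1 was called without KO standard replicate 1.

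Averaged over both genotypes, 17 regions differed after novelty, 16 higher and 1 lower (DESeq2 12, limma-voom 10, and 2134 at an unadjusted p under 0.05). A fit to the KO cohort alone called 102, 81 higher and 21 lower, and offsets fitted to region strength gave 41, 37 higher and 4 lower. Taf4 rose by 0.91 ± 0.13 (adjusted p 0.00048, 0.16 with DESeq2) and Pde10a by 0.35 ± 0.04 (adjusted p 3.7e-05). Nr4a1 and Fosb, which are transcription factor genes induced by neuronal activity, rose by 0.26 ± 0.05 (adjusted p 0.018) and 0.22 ± 0.04 (adjusted p 0.019), and Fos had 0.20 ± 0.05 (adjusted p 0.10). The Nr4a1 call was lost without WT standard replicate 1 (0.126) or 2 (0.137), KO standard replicate 1 (0.0637), WT novelty replicate 2 (0.217) and KO novelty replicate 1 (0.0797) or 2 (0.0882). The Fosb call was lost without WT standard replicate 1 (0.164) or 2 (0.128), WT novelty replicate 2 (0.217) and KO novelty replicate 1 (0.111) or 2 (0.0856). The count was 2 and 5 without WT standard replicates 1 and 2, 8 and 74 without KO standard replicates 1 and 2, 7 and 2 without WT novelty replicates 1 and 2, and 4 and 9 without KO novelty replicates 1 and 2.

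Activity-induced genes moved up as a list after novelty in WT, with 0 of 39 called (4 higher adjusted over the list alone), a median of 0.02 and a camera adjusted p of 0.0093, which became p = 0.301 with an estimated correlation and was lost without WT standard replicate 1 (0.139) or WT novelty replicate 2 (0.849). In KO the list had 0 of 39 called (0 adjusted over the list alone), a median of 0.02 and an adjusted p of 0.0070, with p = 0.238 by an estimated correlation and a loss without KO standard replicate 2 (0.0848) or KO novelty replicate 2 (0.0516). In WT, vascular and pericyte markers were lower as a list (median -0.12, adjusted p 0.0004, p = 0.105 with an estimated correlation), with 0 of 18 called (2 lower adjusted over the list alone).

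Other marker lists moved in the same comparison of WT as the activity-induced genes, Taf4 and Pde10a, with 0 members called by edgeR over all regions. Adjusted over the list alone, 1 striatal, thalamic or hindbrain marker was higher, and 0 members of the other lists were called. Striatal, thalamic and hindbrain markers were higher as a list (median 0.14, camera adjusted p 0.0094). So were interneuron markers (median 0.08, camera adjusted p 0.032). With an estimated correlation these gave p = 0.0883 and p = 0.0651. Pyramidal and granule neuron genes were lower (median -0.07, camera adjusted p 0.00048). So were oligodendrocyte lineage markers (median -0.09, camera adjusted p 0.0093). With an estimated correlation these gave p = 0.27 and p = 0.144. The striatal, thalamic and hindbrain call was lost without WT standard replicate 2 (0.379) or WT novelty replicate 1 (0.364). The interneuron call was lost without WT standard replicate 1 (0.215) or WT novelty replicate 1 (0.108) or 2 (0.0584). The pyramidal and granule neuron call was lost without WT standard replicate 2 (0.37) or WT novelty replicate 1 (0.883). The oligodendrocyte lineage call was lost without WT standard replicate 2 (0.379) or WT novelty replicate 2 (0.0584).

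The second line was compared to ask whether the changes recur in it. In ifKO, H3K4me3 at the shared end of Cacng6 rose from 2.37 ± 0.386 CPM in ifWT to 22.7 ± 3.71 CPM (SD, n = 2 each), a log2 change of 3.27 ± 0.17 (SE, adjusted p 1.3e-14), and that of Gins2 and Gse1 by 3.57 ± 0.30. Wbp11, which encodes a splicing factor (chromosome 6, 136815410 to 136817530), rose from 2.12 ± 0.159 to 14.1 ± 3.03 CPM, a change of 2.73 ± 0.16, and Setd1b from 94.1 ± 1.52 to 136 ± 5.29 CPM, a change of 0.53 ± 0.05. Myo5b, a motor protein gene (chromosome 18, 74442060 to 74443369), fell from 24.3 ± 1.72 to 16.1 ± 0.924 CPM, a change of -0.59 ± 0.10. Camk2a, which encodes a kinase of excitatory synapses (chromosome 18, 60925613 to 60929614), rose from 132 ± 11.2 to 268 ± 6.49 CPM, a change of 1.02 ± 0.06 (adjusted p 3.2e-13) and was 1 of 8 consecutive regions called higher there. D1Pas1 had 3 and 6 counts in ifWT and 3 and 5 in ifKO, and Cyct 2 and 7 in ifWT and 4 and 5 in ifKO, so differences there were within counting error at this depth.

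**Figure D4:**
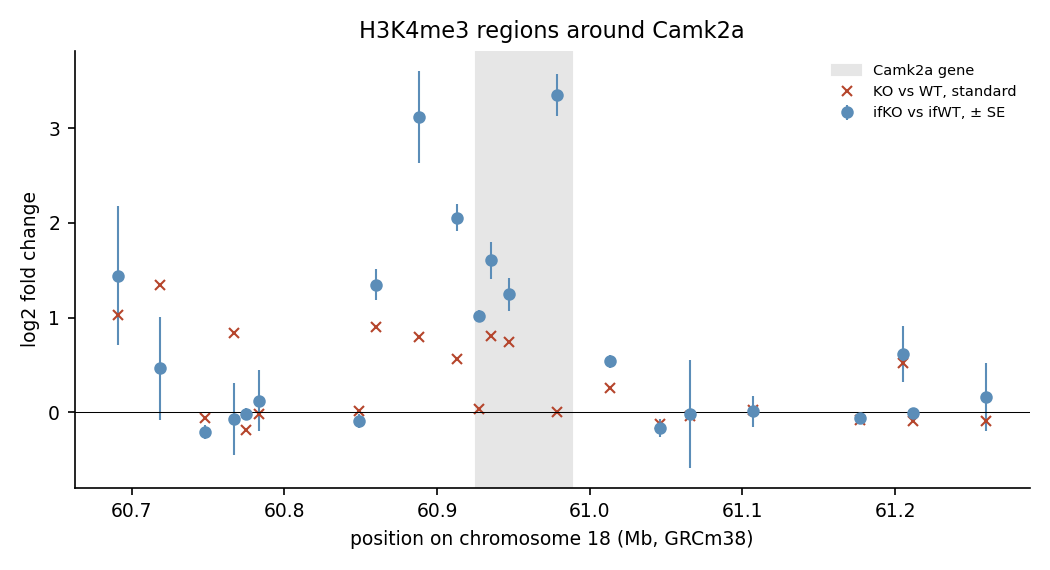
Log2 change of H3K4me3 (vertical axis) in ifKO, with bars of 1 SE, and in KO under standard conditions, shown as crosses, by position on chromosome 18 around Camk2a (horizontal axis). The 8 regions from 60859332 to 61014440 lie between 0.54 and 3.35 in ifKO.

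In all, 1936 regions were called in ifKO by edgeR, 1585 higher and 351 lower, with 1450 by DESeq2 and 1563 by limma-voom. The split was 1017 higher and 42 lower without ifWT replicate 1 (1059 in all), 889 and 46 without ifKO replicate 1 (935), 1072 and 565 without ifWT replicate 2, and 1681 and 891 without ifKO replicate 2. A fit to these groups alone called 1440 regions, 1347 higher and 93 lower, and with offsets fitted to region strength the lower count was 198. The main fit used a spread shared by all groups, although the libraries of ifKO and ifWT varied more than those of the KO cohort. That shared spread could therefore raise the counts for ifKO. Gene ends held 775 higher and 312 lower regions (median -0.04), the inside of genes 550 and 34 (0.06), and the space between genes 260 and 5 (0.11), with camera adjusted p of 0.0003, 0.0087 and 0.0049, all lost with an estimated correlation (adjusted p = 0.243 for each), with offsets fitted to region strength, and without ifWT replicate 1 (0.319) or ifKO replicate 1 (0.305). Germline and meiosis genes had 1 of 21 higher (2 adjusted over the list alone, median 0.15, camera adjusted p 0.022, p = 0.0195 and adjusted p = 0.264 with an estimated correlation, lost without ifWT replicate 2 at 0.0728 or ifKO replicate 2 at 0.0582). Pyramidal and granule neuron genes had 1 of 26 higher (2 adjusted over the list alone, median 0.02, adjusted p 0.015, p = 0.381 with an estimated correlation), and the call was lost without the Camk2a neighbourhood and the 20 largest regions, a setting chosen after seeing the data (0.22), without ifWT replicate 2 (0.173) and without ifKO replicate 1 (0.237). Interferon and innate immune genes had 2 of 23 lower (6 adjusted over the list alone, median -0.16, adjusted p 0.013, p = 0.285 with an estimated correlation, lost without ifWT replicate 2 at 0.178 or ifKO replicate 1 at 0.383). Oligodendrocyte lineage markers were lower (median -0.22, camera adjusted p 0.039, p = 0.22 with an estimated correlation), with 1 of 15 called lower (1 adjusted over the list alone). Choroid plexus and ependymal markers were higher (median 0.12, adjusted p 0.028, p = 0.0311 and adjusted p = 0.264 with an estimated correlation), with 2 of 7 called higher (2 higher and 1 lower adjusted over the list alone). The oligodendrocyte call was lost without ifWT replicate 2 (0.161) or ifKO replicate 2 (0.497), and the choroid plexus call without ifWT replicate 2 (0.0728) or ifKO replicate 1 (0.126).

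Across regions the ifKO changes correlated with those of KO under standard conditions with r 0.397 and rho 0.338, and with those of KO after novelty with r 0.403 and rho 0.376. The first correlation was 0.358 without KO standard replicate 1, 0.328 without ifWT replicate 1 and 0.264 without ifKO replicate 1, and 0.701 for regions with a mean log2 CPM of at least 2. Of the regions called in ifKO, 95.3% had the same sign in KO under standard conditions, and of those called in KO, 85.3% had the same sign in ifKO. All 3 comparisons called 1126 regions higher (17.1 expected from independent calls), 583 of them at gene ends, and 43 lower (0.766 expected). These expected counts take every region as equally likely to be called. The share called varied with region strength, and the tests share 1 fit, so some overlap beyond them would arise without a shared effect. Among the shared rises were Celf3, a gene for an RNA-binding protein of the nervous system, at 2.69, 2.25 and 2.42 log2 in KO under standard conditions, KO after novelty and ifKO, Depdc5, a gene for an inhibitor of mTORC1 signalling, at 2.92, 2.46 and 2.45, and Klhl29 at 2.27, 2.30 and 2.42. Myo5b fell in all 3, with changes of -0.47, -0.68 and -0.59.

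**Figure D5:**
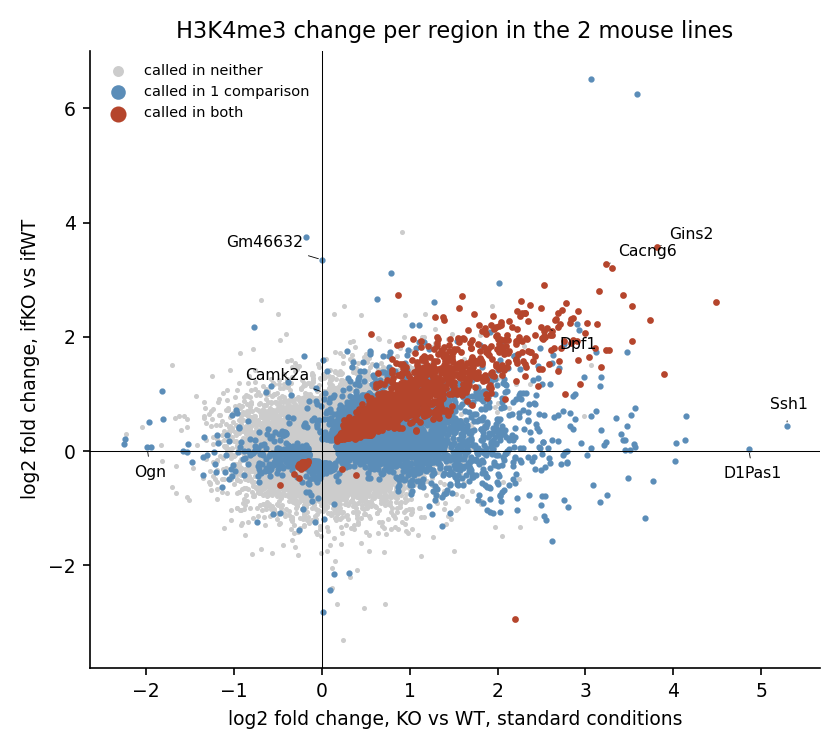
Log2 change of H3K4me3 per region in KO under standard conditions (horizontal axis) against ifKO (vertical axis), where points are regions. Across the 35955 regions r was 0.397.

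The lines were also compared directly, as the KO effect under standard conditions minus the ifKO effect. H3K4me3 at Ssh1 differed by 4.85 log2 (adjusted p 0.0016), with 0.356 CPM in ifKO and 0.259 CPM in ifWT, and Camk2a differed by -0.99 (adjusted p 4.1e-08). Wbp11 rose in KO by 0.87 and in ifKO by 2.73, a difference of -1.86 (adjusted p 6.5e-07). In total 252 regions differed by edgeR, 234 with the higher effect in KO and 18 with the higher effect in ifKO (DESeq2 145, limma-voom 99, and 3040 at an unadjusted p under 0.05). The count was 165 without WT standard replicate 1, 94 without WT standard replicate 2, 163 without KO standard replicate 1 and 145 without ifWT replicate 2, with 35, 6, 17 and 41 of these higher in ifKO, against 93 without ifKO replicate 2. The lines also differ in background strain by the labels.

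Binding of Kdm5C and H3K4me1 was compared between 1 WT and 1 KO library each, without replicates and so without a test. Summed over the deposited regions, Kdm5C signal was 3835440 covered bases in WT and 852275 in KO, a ratio of 4.50, and 91.0% of these regions lay at gene ends. After scaling to the file total, which removes that ratio, the median log2 ratio of KO to WT was 0.11 (95% interval 0.0232 to 0.198) over 610 regions with at least 50 read equivalents. It was -0.39 (-0.65 to 0.00079) over the 86 regions with at least 100, and -2.06 without scaling over the 610. The prior was added before scaling, where the 610 regions had medians of 54.4 read equivalents in WT and 13.0 in KO. It therefore raised the KO values by a larger share and shifted the scaled ratios of these regions toward KO. A scaled median as small as 0.11 can arise in part from that shift. Both intervals treat regions as independent and leave out variation between libraries, so neither bears on whether KO and WT mice differ. Signal was lowest in KO relative to WT at the end of Zfp438, a zinc finger gene (chromosome 18, 5334350 to 5334850), with 133 and 2.02 read equivalents in WT and KO, and at Tmem179, with 57.7 and 0.16. After scaling it was highest in KO relative to WT inside Pisd-ps1, with 55.1 and 49.6 read equivalents in WT and KO and a scaled log2 ratio of 2.02 (1.45 to 2.61). At Kmt2c, an H3K4 methyltransferase gene, there were 28.4 and 23.6 read equivalents and a scaled log2 ratio of 1.91 (1.1 to 2.79). Without scaling, KO was below WT in 100% of the 610 regions, these included. H3K4me1 signal totalled 645195 covered bases in WT and 396072 in KO, and 2 regions reached the minimum, Pisd-ps1 at 1.01 (0.43 to 1.62) and Klhl35 at -0.56 (-1.55 to 0.25).

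H3K4me3 was then compared at the 83 regions that overlapped Kdm5C signal at least 2-fold higher in WT than in KO after scaling. Scaled Kdm5C signal was at least 2-fold lower in KO in 82 of the 610 Kdm5C regions and at least 2-fold higher in 83, so the set stems from 1 tail of a nearly even spread between single libraries. In KO under standard conditions 26 of them rose and 0 fell (median 0.04, camera p 0.000113), after novelty 26 rose and 3 fell (camera p 0.000769), and in ifKO 14 rose and 1 fell (camera p 0.0013, and 0.051 without ifWT replicate 2). The median under standard conditions was 0.0159 without KO standard replicate 1 and 0.0540 without replicate 2. With an estimated correlation p was 0.153, 0.2 and 0.224. For all regions overlapping the deposited Kdm5C regions, a set chosen after seeing the data, the medians were -0.05, -0.06 and -0.03 in the same order, opposite in sign. With ratios taken without scaling, also chosen after seeing the data, the median under standard conditions was -0.01.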

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

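Of the tests below, only the comparisons of the 8 libraries of the KO cohort with other groupings and the test of whether the regions at least 2-fold higher keep their call with offsets fitted to region strength were chosen before their result was seen. The tests around Camk2a, those of strain blocks and of region strength for the difference between the lines, and that of the median shift of weak regions were chosen after it. The genes, lists and the count of regions that differ between the lines are given for a difference between groups, in which the KO effect under standard conditions was tested against the ifKO effect, or the genotype effect after novelty against that under standard conditions. The shift of weak against strong regions and the comparisons with other groupings concern the KO and novelty effects themselves and no such difference.

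H3K4me3 at Camk2a differed by -0.99 log2 between the lines, as KO effect minus ifKO effect (adjusted p 4.1e-08), with changes of 0.03 in KO and 1.02 in ifKO. That difference is what singled out this region and is no separate test of an effect of Kdm5c loss shared by both lines, but after novelty, in libraries that took no part in it, the KO change was 0.13 (adjusted p 0.156), which argues against a shared effect of like size at the gene end. Camk2a was in a run of 8 consecutive regions called higher in ifKO, from 60859332 to 61014440 on chromosome 18, with a median of 1.48, while the longest other run and the longest in 1000 shuffles each held 5, and the 46 other regions within 1 Mb had a median of -0.02. Within the run, Gm41744 (0.90), Arsi (0.56), the regions inside Camk2a (0.80 and 0.74) and Slc6a7 (0.25) were also called higher in KO under standard conditions. Gm41745 (0.79), the Camk2a end (0.03) and Gm46632 (0.01) were not. Only Arsi, the Camk2a end and Gm46632 were called as different between the lines. Additional copies of a DNA segment around Camk2a in the ifKO mice are a candidate explanation that stays open, although changes from 0.54 to 3.35 within the run and a median of 0.65 for the same regions in KO leave room for others, and the sources used here do not describe how the line was made. A regulatory change in the ifKO line alone was not tested.

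The lines differed in 252 regions, 234 of them with the higher effect in KO. With offsets fitted to region strength, 191 of the 252 were still called in the same direction. These offsets remove only the average change at each strength, whose medians ran from -0.02 to 0.09 log2 for this difference. A difference of at least 2-fold was reached by 166 regions with the higher effect in KO and 11 with the higher effect in ifKO. An average dependence of the libraries on strength is thus argued against as the whole cause for those 191. Dependence that differs between regions of like strength would remain and cannot be told apart from other causes. Genome blocks from another strain, which the mixed C57 and 129 background of the KO cohort could bring, cannot be told apart from other causes, because 85 of the 252 had another called region of the same direction between 10 kb and 1 Mb away, against a 95th percentile of 60 in 10000 random draws but 86 in draws matched on direction. The count of regions that differed was 94 without WT standard replicate 2, 145 without ifWT replicate 2, 163 without KO standard replicate 1 and 165 without WT standard replicate 1, and the 18 with the higher effect in ifKO became 6, 41, 17 and 35 in that order and 93 without ifKO replicate 2. A biological difference between a KO and an ifKO line stays open and was not tested separately from strain.

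Weak regions were higher and strong regions lower in KO, from a median of 0.19 to one of -0.09 log2 under standard conditions. Of the 1421 regions called at least 2-fold higher, 980 stayed called at least 2-fold higher with offsets fitted to region strength. These offsets remove only the average change at each strength, which was small against a 2-fold change. Background that differs between regions of like strength would remain. Unequal background between the libraries as the whole cause of these regions therefore cannot be told apart from others. For the median shift of the weak regions the same explanation cannot be told apart from others. A background common to the genome might give like medians in the 3 position classes. These lay within 0.0619 log2 of each other under standard conditions but 0.108 ± 0.021 (SE) apart after novelty, the latter between the limits set for and against this explanation. That SE treats regions as independent and leaves out variation between libraries. A wider spread of H3K4me3 beyond promoters after loss of the demethylase is a biological alternative, and no input libraries were used here that could tell it from background.

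For the KO effect averaged over standard conditions and novelty, the real grouping of the 8 libraries called 12304 regions in a fit to these libraries alone. The highest other grouping called 1, so 1 of 35 groupings gave as many regions, the smallest share possible here. The other groupings were fitted without genotype as a term, so the genotype difference entered their spread and could lower their counts. That comparison therefore cannot exclude chance. For novelty averaged over genotypes chance is not excluded, since 2 of 34 groupings gave as many regions. These fits had genotype as an additive term in place of the group means that gave 102 regions in the same libraries, with 80 called in the real grouping and 91 in the grouping of both WT standard libraries with KO standard replicate 1 and KO novelty replicate 1.

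Positive differences, with the KO effect above the ifKO effect, were found at Ssh1 (4.85, adjusted p 0.0016), D1Pas1 (4.82, 0.011), Gm16013 (4.29, 6.5e-07), Gm33919 (4.20, 0.0002), Cdk19 (3.90, 0.0009) and Gm29642 (3.50, 0.0013). Differences at regions of Gm41429 (3.09), Lpgat1 (3.08), LOC108167736 (3.04), A230009B12Rik (3.01) and LOC102643083 (2.98) had adjusted p from 3.3e-05 to 0.00081. For Dym the difference was 2.52 (0.0026), for 4930452G13Rik 2.55 (0.031), for Zfp532 1.44 (0.046), where both lines rose, for Gpr17 1.02 (0.0096) and for Tex14 0.46 (0.028). At En2 the difference was 0.82 (0.0016), with changes of 0.39 in KO and -0.43 in ifKO, at Sirt1 0.55 (0.0076), with 0.23 and -0.32, and at Nfyb 0.40 (0.049), with 0.03 and -0.37, so that the change in ifKO was the larger in size at all 3. D1Pas1 was lost without WT standard replicate 2 (0.098) or ifWT replicate 2 (0.272), Gm29642 without ifWT replicate 2 (0.251), and Gpr17 without WT standard replicate 2 (0.0993) or ifWT replicate 1 (0.0874). Tex14 was lost without WT standard replicate 1 (0.0785) or 2 (0.178), KO standard replicate 1 (0.0767) or 2 (0.057), ifWT replicate 1 (0.143) and ifKO replicate 2 (0.0921).

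Negative differences, with the KO effect below the ifKO effect, were found at Gm46632 (-3.34, adjusted p 6.9e-07) and Arsi (-1.49, 5.6e-05), both in the run around Camk2a, and at Gm46874 (-2.04, 0.0024), Wbp11 (-1.86, 6.5e-07), Henmt1 (-1.60, 0.008), Gm45871 (-1.38, 0.016) and Ankrd6 (-1.34, 0.046). They were also found at Ogn (-2.05, 0.015), Zfp972 (-2.01, 0.017), Trf (-1.69, 0.046) and Gm35479 (-1.03, 0.030), where the KO changes under standard conditions were -1.99, -1.95, -0.98 and -1.09. After novelty the KO changes there were -1.46 (adjusted p 0.00064), -0.52 (0.27), -0.15 (0.74) and -1.04 (1.7e-05). Henmt1 was lost without KO standard replicate 1 (0.0658). Gm45871 was lost without WT standard replicate 2 (0.243), KO standard replicate 2 (0.116), ifWT replicate 1 (0.0715) or ifKO replicate 1 (0.136), and Ankrd6 without WT standard replicate 1 (0.0758) or 2 (0.319), KO standard replicate 1 (0.194), ifWT replicate 1 (0.127) or 2 (0.168) or ifKO replicate 1 (0.153). Ogn was lost without WT standard replicate 2 (0.126), KO standard replicate 1 (0.054), ifWT replicate 2 (0.0867) or ifKO replicate 2 (0.15), and Zfp972 without WT standard replicate 2 (0.141), KO standard replicate 1 (0.148), ifWT replicate 1 (0.0906) or ifKO replicate 1 (0.0765). Trf was lost without WT standard replicate 1 (0.137) or 2 (0.165), KO standard replicate 2 (0.205), ifWT replicate 1 (0.212) or ifKO replicate 2 (0.161).

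As lists, the KO effect was higher than the ifKO effect for germline and meiosis genes (median 0.46, camera adjusted p 0.00037, p = 0.0042 and adjusted p = 0.0714 with an estimated correlation), and 2 of 21 members were higher (3 adjusted over the list alone). It was lower for pyramidal and granule neuron genes (-0.0783, adjusted p 4.8e-05, p = 0.207 with an estimated correlation), vascular and pericyte markers (-0.14, adjusted p 0.0025, p = 0.163) and ribosomal protein genes (-0.0563, adjusted p 0.0079, p = 0.288). After novelty the genotype effect was higher than under standard conditions for pyramidal and granule neuron genes (0.0642, adjusted p 0.033, p = 0.42 with an estimated correlation) and oligodendrocyte lineage markers (0.11, adjusted p 0.0025, p = 0.0856) and lower for striatal, thalamic and hindbrain markers (-0.16, adjusted p 0.033, p = 0.112).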

How the results depend on the processing

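Chosen only after the data were seen were the tests on the Kdm5C set without a ratio, on the set from unscaled ratios, and without the Camk2a neighbourhood and the 20 largest regions. Of 4581 values of named regions under alternatives other than leaving out 1 library, 4196 kept direction and side of the threshold, 340 lost the call, 38 gained one and 7 moved. Of 2076 with 1 library left out, 1662 kept both, 409 lost the call and 5 gained one. For lists 1056 of 1105 kept both, 26 lost the call and 23 gained one, and for position classes 240 of 260 kept both, 19 lost the call and 1 gained one. With 1 library left out, 287 of 340 list values and 72 of 80 class values kept both. Replicate numbers showed little sign of pairing the libraries, whose deviations correlated between groups from -0.036 to 0.057. The labels do not state whether they pair, and counting error lowers such correlations, so pairing is not excluded. GC correction, alone or with the replicate block, was not run, and camera could not be run on DESeq2. Regions with a handful of counts, such as those of D1Pas1 and Cyct in WT, are limited by depth.

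With an added minimum log2 change of 0.5, which can only lower counts, 2753 regions were called in KO under standard conditions, 3073 after novelty, 4238 in their average, 1188 in ifKO, 1 for novelty in WT and 5 for novelty averaged over genotypes. A threshold of 0.1, which can only raise counts, gave 6 for novelty in WT, 1 in KO, 31 averaged, 397 for the difference of the lines and 25 list calls. At a mean log2 CPM of at least 2, which tests fewer regions, there were 1 for novelty in WT, 7608 for the averaged KO effect, 102 for the difference of the lines and r 0.701 between KO and ifKO. List and class calls, 15 and 9, are sums over KO against WT under standard conditions and after novelty, novelty in WT and in KO, and ifKO against ifWT, without averages, interaction or difference of the lines. For the rest the cause was not tested. DESeq2 and limma-voom called 1 each for novelty in WT and in KO, and 145 and 99 for the difference of the lines, and limma-voom 10 for averaged novelty and 29 lists against 15. Fits to the compared groups alone gave 106 for novelty in WT, 102 averaged, 149 for the difference of the lines and r 0.458. Fits to the same cohort gave 47 for novelty in WT, 5 in KO, 102 averaged and r 0.452. Loess offsets gave 6 for novelty in WT, 1 in KO, 41 averaged and 1 class call against 9. Novelty in KO had 1 with library totals and 1 without the Camk2a neighbourhood and the 20 largest regions, and novelty in WT 4 with the replicate block.

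List calls were 2 with an estimated correlation, 7 by fry for a shared direction and 34 by fry for either direction, and class calls 0 with an estimated correlation and 4 by fry for a shared direction. Between KO and ifKO, r was 0.521 over regions called in either. The median of the Kdm5C set was 0.0394 in KO under standard conditions, 0.0405 after novelty and 0.0424 in ifKO, each without a call with an estimated correlation. It reversed to -0.0526, -0.0555 and -0.0348 for any region of the Kdm5C files and became -0.0129, 0.00312 and 0.000257, also without a call, with unscaled ratios. The median Kdm5C ratio reversed to -2.06 without scaling and was -0.39 at 100 read equivalents or more.

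Leaving out 1 library at a time gave 1984 to 3515 regions in KO under standard conditions, 2239 to 4846 after novelty, 7931 to 10861 averaged, 935 to 2572 in ifKO, 94 to 362 for the difference of the lines, 0 to 3 for novelty in WT, 0 to 4 in KO, 2 to 74 averaged and 0 to 1 for the interaction. It gave 10 to 21 list calls, 6 to 11 class calls, r from 0.264 to 0.386, and Kdm5C set medians of 0.0159 to 0.0540, 0.0421 to 0.0723 and 0.0295 to 0.0746 in the same order. Pyramidal and granule neuron genes reversed to 0.0622 for novelty in KO without KO standard replicate 1, in a range from -0.0475, and to 0.0153 for novelty in WT without WT novelty replicate 1, in a range from -0.156.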

Other observations

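Of the tests in this part, only the count of differing regions by chromosome was chosen after the result was seen. In ifKO, the shared end of Ccdc153, a gene of ciliated cells, and Pdzd3 rose by 1.43 ± 0.24 log2, and Sox18 by 0.57 ± 0.08.

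The region with the most counts (chromosome 2, 98666198 to 98667456) took 0.744% to 1.09% of the counts of each KO-cohort library and 1.95% to 3.6% of those of each library of the ifKO cohort. Of the 252 regions in which the lines differed, chromosome 9 held 30 (13.2 expected from its number of regions), chromosome 18 held 17 (8.6 expected) and the X chromosome 1 (6.73 expected). Those on chromosome 18 include Arsi, the Camk2a end and Gm46632, which lie in the single run around Camk2a.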
